A study of Mus musculus with 9 samples.

How the data were processed

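RNA-seq libraries of 9 samples were described by the labels as 3 control, 3 JICD1 and 3 NICD1 libraries. Bowtie2, BWA and the mouse build mm9 are named in the submitters' processing notes, with no version or role. How reads were counted, and how the 3 libraries of a group were combined, is not given in the sources used here. The 2 deposited tables hold the authors' own comparisons, with a log2 ratio of the transfected group over control per gene, per the file headers. Each deposited table also holds a score between 0 and 1 that the authors call Probability, per the file headers. The score had a Spearman correlation with the absolute log2 ratio of 0.31 in the JICD1 table and 0.33 in the NICD1 table across genes, so large ratios can have low scores. It is not a p-value, and its method is not stated. The tables held 0 unused numeric columns.

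A replicate test on counts had been planned. The tables hold 1 ratio per gene and no value per library, so no test, standard error, p-value, replicate block or left-out library could be computed, and depth is unknown. Genes with a score of 0.8 or more were called scored; the threshold was set after the data were examined. The rule for named genes was fixed before the data were examined: 11 genes always, the 8 largest ratios in each direction, and up to 4 scored members per list. The rule asked for a minimum FPKM for the largest ratios; with no FPKM here, the score of 0.8 took its place. Genes without an established symbol were passed over, and a few genes that the rule names are not reported here. The JICD1 over NICD1 value is the difference of the deposited log2 ratios.

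Names were taken from the tables and from NCBI and GENCODE vM21 annotation of GRCm38, which gave names to 18681 of 18971 genes of the JICD1 table and 18998 of 19287 of the NICD1 table. That assembly is not mm9; it served for names, chromosome membership and gene order, and no coordinate is given. A chromosome was found for 98.3% of genes and a transcript GC content for 97.1%. Older symbols were matched for Ctgf (Ccn2), Cyr61 (Ccn1) and Ero1l (Ero1a).

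The tables give a ratio for every gene and mark no floor; that a floor replaced zeros was inferred from the values. There were 694 genes with the same negative ratio in both deposited tables within a tolerance of 1e-06, and 1 gene with the same positive ratio; equal negative ratios were taken to place both transfected groups at a common floor. Genes lying on the score curve of these genes, within 0.002 (0.01 above a log2 of 6) and with an absolute log2 ratio of at least 1, were taken to have a group at the floor, and no fold is given for them. The curve ends at a log2 of 9.45, so a larger ratio decides nothing, and the control of such a gene was called from the other table where that table's ratio lay on the curve. Of 507 genes at 1 or more in both tables with the control on the curve in one, 460 (90.7%) were on it in both. The floor simulations used an assumed score, the mean rank of the absolute log2 ratio and of the absolute difference between group values. How the deposited score is made is not stated, so the simulated rates need not hold for it. On simulated fine-grained values of 16180 genes, 99.4% of the JICD1 floor calls were right, with 5 equal positive ratios. On simulated coarse values of 16110 genes only 74.5% were right, with 252 equal positive ratios. The limit of 1 on the ratio was added after a first simulation had shown false calls among small ratios.

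Mean expression is not in the tables. In its place an abundance rank was used, the rank of a gene's score among the 300 genes nearest in absolute log2 ratio. The ranks of the 2 tables had a Spearman correlation of 0.71 across genes, and the rank had one of 0.86 with the true abundance on simulated fine values and 0.71 on coarse values. The simulated correlations rest on the same assumed score, so how well the rank follows abundance in the real data is unknown. Matching on the rank is therefore approximate, and single abundant genes can be ranked low.

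The 17 gene lists and 6 cell type marker lists were fixed before the data were examined. Each list's median was placed among 10000 random lists drawn with replacement from 10 abundance bins (seed 7); the percentile describes these tables and is not a p-value, and it takes no account of correlation between the genes of a list. Lists with fewer than 5 measured members were left out. A list can have different measured members in each comparison, as 789 genes had a ratio only for JICD1 and 1105 only for NICD1. Of these, 779 and 1098 lay above 0, which tends to raise the median of a list that holds them. On the real ratios of 18182 genes with simulated lists of 20 genes, 6% of the JICD1 lists and 3.5% of the NICD1 lists lay outside the central 95% with no shift, and 92% and 98% with a shift of 0.5. The relabelling of group values (100 draws, 20 abundance bins) gave 97 to 128 same-direction genes on simulated independent groups, where 125 were present.

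Alternatives were an absolute log2 ratio of at least 1, which had been planned, and others chosen after the data were examined: scores of 0.9 or 0.7, leaving out genes at the floor or on shifted chromosomes, subtracting chromosome medians, random lists without matching, the tables' own symbols only, and genes in the upper part of the abundance ranks (0.5 or more). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.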

Results

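RNA was sequenced from cultured murine astrocytes that lack Ink4a, the tumour suppressor locus product that restrains the cell cycle. The cells had been transfected with an empty puromycin-resistance vector (control), with a vector for HA-tagged JICD1, or with a vector for NICD1. JICD1 is the intracellular part of the Notch ligand Jagged1, and NICD1 is the intracellular part of the receptor Notch1, which acts in the nucleus as a transcriptional activator. There were 3 libraries in each of the 3 groups, 9 in all. The values analysed were those of the authors' deposited tables, one for each construct against control, with 1 log2 ratio and 1 score between 0 and 1 per gene. No value per library was used here, so no ratio below has a replicate error or a p-value, and the depth of the libraries is unknown. Genes with a score of 0.8 or more are called scored genes; this threshold was chosen after the data were examined and is not a significance level. Words such as higher and lower describe the direction of a ratio and carry no test.

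The first comparison asked which genes differed between cells given JICD1 and control cells. Among the 18971 genes of the authors' deposited table, 533 were scored, 203 higher and 330 lower in the JICD1 group. In the authors' deposited table the largest scored log2 ratios above 0 included those of Ctnnd2 (9.92), Pou3f2 (9.18), Slc6a15 (9.04), Gpc4 (8.96), Ildr2 (8.60), Tram1l1 (8.57) and Ptchd4 (8.42). Pou3f2 encodes a neural transcription factor, and its control group was inferred from the ratio and score to lie at a common floor, so no fold is given. The authors' deposited tables mark no floor; every floor named here is such an inference. The largest below 0 in the authors' deposited table were Il1rn (-10.23), Rbp2 (-9.45), Crip1 (-9.37), Syt7 (-9.28), Cxcl12 (-9.16), Plac8 (-8.88), Scara5 (-8.84) and Dcn (-8.67). For Rbp2, Scara5 and the proteoglycan gene Dcn the JICD1 group was inferred to lie at the floor. The ratio of Il1rn lies beyond the range of the inference, so whether its JICD1 group was at the floor is undecided.

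The gene of the ligand itself did not follow the label. Jag1 had a log2 ratio of -1.39 and a score of 0.759 in the JICD1 comparison of the authors' deposited table, a value 2.63-fold lower than control. The construct encodes a fragment of the protein, and whether its transcript adds to the Jag1 value is not given in the sources used here. The group is therefore called the libraries labelled JICD1, and every direction below rests on that label. Notch1 had a log2 ratio of 1.33 with a score of 0.735 in the authors' deposited table.

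Matrix genes were lower in the libraries labelled JICD1. Of 22 measured members of the extracellular matrix list, 20 had ratios below 0, and 10 were scored lower and none higher; the list median was -1.16, below all 10000 random lists matched on abundance rank. In the authors' deposited table the collagen VI genes Col6a1 and Col6a2 had log2 ratios of -5.76 and -4.97, and the collagen cross-linking enzyme genes Lox and Loxl2 had -4.24 and -3.38. Col1a2 was an exception in the authors' deposited table, at 0.92 with a score of 0.751. The fibroblast and pericyte markers moved with this list: all 6 measured members lay below 0, with a median of -2.98, among them Pdgfrb at -2.17 and Anpep at -3.79 in the authors' deposited table.

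Invasion and mesenchymal genes had a median of -1.05, also below all matched random lists, with 7 of 23 scored lower and 1 higher. The authors' deposited table gave Plau, the urokinase gene, a log2 ratio of -4.79 (27.6-fold lower), Snai1 -3.55 and Mmp9 -3.46. Snai2 went the other way in the authors' deposited table, at 4.45. Of 21 TGF-beta and SMAD targets, 19 lay below 0 and 7 were scored lower; their median of -0.66 stood at percentile 0.07 of the random lists. Tgfbi (-4.88), Ccn2 (-4.01), Acta2 (-3.74) and Pmepa1 (-2.80) were the scored members with the largest absolute ratios in the authors' deposited table. Bambi, named after its value was seen, stood at 4.26 with a score of 0.575 in the authors' deposited table.

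The inflammatory lists also had medians below 0, with members going both ways. The NF-kB list had a median of -0.69 at percentile 0.46, with 3 of 17 members scored lower. In the authors' deposited table Il1rl1 stood at -4.95, Ccl7 at -4.49 and Ccl2 at -1.88. Of the 17 NF-kB members 5 lay above 0. Among them Cxcl5, named after its value was seen, stood at 4.67 with a score of 0.773 in the authors' deposited table. The interferon list had a median of -0.39 at percentile 0.40, but 13 of its 27 members lay above 0 and the single scored member, Bst2, was higher at 1.33 in the authors' deposited table. Immediate early genes had a median of -0.44 at percentile 1.07, with 1 of 15 scored, Egr3 at -2.86 in the authors' deposited table. The p53 and growth arrest list had a median of 0.49 at percentile 99.2. Its scored members in the authors' deposited table were the cell cycle inhibitor gene Cdkn1a at 2.35 (5.09-fold higher) and Perp at -1.22.

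Notch targets did not stand apart in the libraries labelled JICD1. Their median was 0.14, at percentile 74.7, their mean was -0.08, and none of 11 was scored; Hes1 was at -0.54, Hey1 at -1.84, Hey2 at 1.14 and Nrarp at -0.96 in the authors' deposited table. No member of the 22 Notch pathway components was scored, with a median of -0.13 at percentile 9.45. The neural stem list had a median of 0.21 at percentile 86.9 and 4 scored members in the authors' deposited table, Pou3f2 and Sox2 (1.45, 2.72-fold) higher and Sox4 (-1.55) and Itga6 (-1.05) lower. Twist1 stood at 0.96 with a score of 0.745 in the authors' deposited table. Lists of the cell cycle (percentile 53.6), the unfolded protein response (42.0), DNA methylation (51.4), cholesterol synthesis (27.3), hypoxia and glycolysis (92.1), imprinted genes (90.5) and mitochondrial and nuclear RNA (49.4) lay inside the central 95% of random lists. Among these the scored members in the authors' deposited table were Bnip3 at 1.27, Igf2r at 1.13, Impact at 1.19 and Snrpn at -7.91, and the imprinted list had a median of 0.45 but a mean of -0.22.

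Of the other cell type markers, the astrocyte list had a median of -0.59 at percentile 0.53, with Clu at -3.88 and Nfia at 3.77 in the authors' deposited table; with the tables' own symbols only, its median turned to 0.022 (percentile 46.1, 7 members). The neuron list had a median of 0.57 at percentile 98.1, with Map2 at 3.02 and Tubb3 at -2.16 in the authors' deposited table. The microglia list (median -0.61, percentile 1.76) had 1 scored member, Tmem119, at -8.48 in the authors' deposited table, and the endothelial list (median 1.15, percentile 99.1) had none. The oligodendrocyte list had a median of -0.34 at percentile 7.51. In all, 12 of 23 lists lay outside the central 95%, where 1.15 would be counted by chance if the genes within each list varied independently. The percentiles take no account of correlation within a list, so 12 against 1.15 is not a test. The p53, immediate early, astrocyte, neuron and microglia results came inside it under at least 1 alternative; the immediate early list did so after chromosome medians were subtracted.

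The second comparison asked which genes differed between cells given NICD1 and control cells. Of the 19287 genes of the authors' deposited table, 503 were scored, 316 higher and 187 lower. The largest scored log2 ratios above 0 in the authors' deposited table were Cdkn2b (11.24), Has2 (10.13), Creb3l1 (9.96), Pcdh7 (9.48), Bhlhe22 (9.43), Eya4 (9.23), Igfbp2 (9.06) and Fndc3c1 (9.03). Has2 encodes a hyaluronan synthase; for Bhlhe22 and Eya4 the control was inferred to lie at the floor, and for Cdkn2b this was inferred from its JICD1 ratio of 1.81 in the authors' deposited table, since its NICD1 ratio lies beyond the range of the inference. The NICD1 ratio of Creb3l1 also lies beyond that range. Its JICD1 ratio of 0.42 in the authors' deposited table is too small for the inference, so its control is undecided. Below 0 the authors' deposited table listed Rbp2 (-9.45), Gpnmb (-8.53), Ndp (-8.53), Gprin1 (-7.84), Cldn9 (-7.82), Ces2g (-7.51), Dnajc27 (-7.33) and Zfp982 (-7.23). For Rbp2, Ndp and Gprin1 the NICD1 group was inferred to lie at the floor.

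Notch targets were higher with NICD1. Their median was 1.66, at percentile 99.9, and 8 of 10 measured members lay above 0. Hes1 was scored at 1.58 (3.00-fold) and Nrarp at 2.84 in the authors' deposited table. Hey1 (2.19) and Hey2 (4.46) had scores of 0.709 and 0.442 in the authors' deposited table, and the control was inferred to lie at the floor for Hey2. Notch1 at 1.77 (3.41-fold, score 0.815) and Jag1 at 1.36 (2.56-fold, score 0.819) were the scored Notch pathway components of the authors' deposited table; that list as a whole had a median of 0.01 at percentile 60.3. As with JICD1, how much of the Notch1 value comes from the construct is not given in the sources used here. Hes5 and Heyl were looked for but matched no gene with a ratio.

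**Figure D1:**
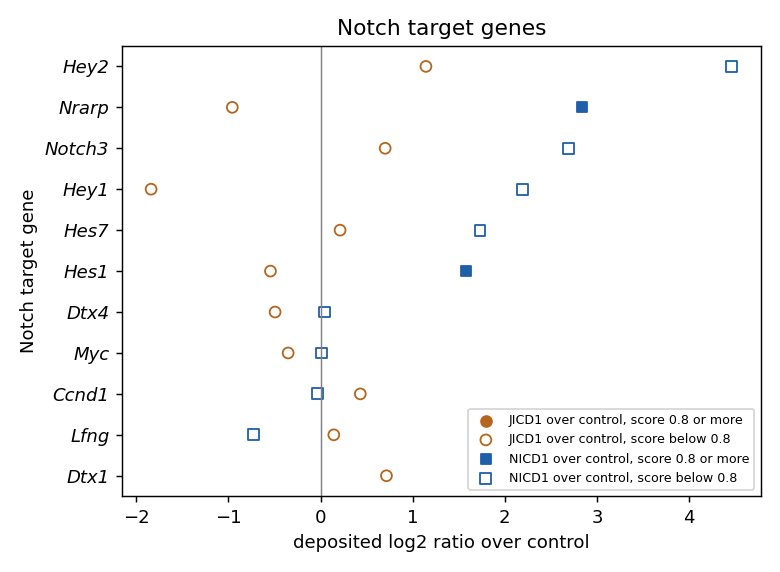
Deposited log2 ratio over control (x axis) of each measured Notch target gene (y axis), with circles for JICD1 and squares for NICD1 and filled symbols for scores of 0.8 or more. The filled symbols are the NICD1 values of Hes1 (1.58) and Nrarp (2.84), and no JICD1 value is filled; Dtx1 has no NICD1 value.

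Several lists that were lower in the libraries labelled JICD1 were higher with NICD1. TGF-beta and SMAD targets had a median of 0.50 at percentile 99.0, with 6 of 21 scored higher and 1 lower. The authors' deposited table listed the smooth muscle gene Tagln at 4.21, Ltbp2 at 3.66 and Acta2 at 1.71 (3.26-fold), against Tgfbi at -2.92. Invasion genes had a median of 0.63 at percentile 99.8, with 7 of 23 scored higher and none lower. Mmp13 (6.17), Mmp10 (5.98), Snai2 (4.50) and Cdh11 (4.33) were the scored members with the largest absolute ratios in the authors' deposited table. Matrix genes were mixed: the median was 0.48 at percentile 99.0, and 4 of 22 were scored higher and 3 lower. Tnc (5.86), Col1a2 (1.80) and Thbs1 (1.78) were higher and Col3a1 (-3.31), Col6a1 (-1.27) and Col6a2 (-1.22) lower in the authors' deposited table. Fibroblast and pericyte markers had a median of -1.56 at percentile 0.19, with Dcn at -5.08 in the authors' deposited table.

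Hypoxia and glycolysis genes had a median of 0.76 at percentile 99.8 with 5 of 19 scored higher, among them Pdk1 (3.92), Bnip3 (1.41), P4ha2 (1.20) and P4ha1 (1.15) in the authors' deposited table. Cholesterol synthesis genes had a median of -0.65 at percentile 0.05 and 17 of 19 lay below 0. Dhcr7, a reductase of late sterol synthesis, was the scored member at -2.05 (4.14-fold lower) in the authors' deposited table. NF-kB genes had a median of 0.80 at percentile 99.9, with Il33 (4.93), Vcam1 (1.14) and Ptgs2 (1.09) scored higher and Ccl7 (-1.97) lower in the authors' deposited table. Of the 20 measured NF-kB members, Il6, Cxcl2, Ccl20 and Tnf had no JICD1 ratio and a control inferred at the floor. None of these was scored, and without genes at the floor the NF-kB list stayed above the central 95%. The interferon list (median 0.66, percentile 99.9) had 1 scored member, Cxcl10 at 1.93 in the authors' deposited table. Immediate early genes had a median of 0.51 at percentile 97.7, with Egr1 (1.79), Ier3 (1.18) and Dusp1 (1.18) scored in the authors' deposited table.

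In the p53 and growth arrest list (median 0.04, percentile 69.5), Cdkn2b, Cdkn2a (7.59) and Cdkn1a (1.57) were scored higher and Perp (-4.28) lower in the authors' deposited table. Cdkn2a is the Ink4a locus itself. Its control was inferred to lie at the floor, and it had no ratio in the JICD1 comparison. Whether the reads lie in the part removed from these cells is not given in the sources used here, so the value does not check the genotype. The neural stem list had a median of 0.43 at percentile 98.2 with no scored member; Sox2 stood at 0.92 and Twist1 at -0.32 in the authors' deposited table. Lists of the cell cycle (percentile 18.1), the unfolded protein response (92.2), DNA methylation (18.4), imprinted genes (62.8) and mitochondrial and nuclear RNA (27.6) lay inside the central 95%. The imprinted genes Snrpn (-2.40) and Mest (-1.77) were scored in the authors' deposited table.

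Among cell type markers the neuron list had a median of 2.76 over 7 measured members, above the central 95% of random lists, with Gap43 (3.96), Map2 (3.95) and Stmn2 (2.76) scored higher and Tubb3 (-3.67) lower in the authors' deposited table. The astrocyte list had a median of -0.69 at percentile 0.10, with Clu (-2.30) and Sox9 (-1.65) scored in the authors' deposited table; with the tables' own symbols only, its median turned to 0.70 (percentile 93.1, 7 members). The microglia (median 0.80, percentile 98.7) and endothelial (median 0.84, percentile 98.2) lists had no scored member, and the oligodendrocyte list had a median of 0.18 at percentile 80.2. In all, 15 of 23 lists lay outside the central 95%. The neural stem, matrix, interferon, NF-kB, immediate early and endothelial results came inside it under at least 1 alternative.

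**Figure D2:**
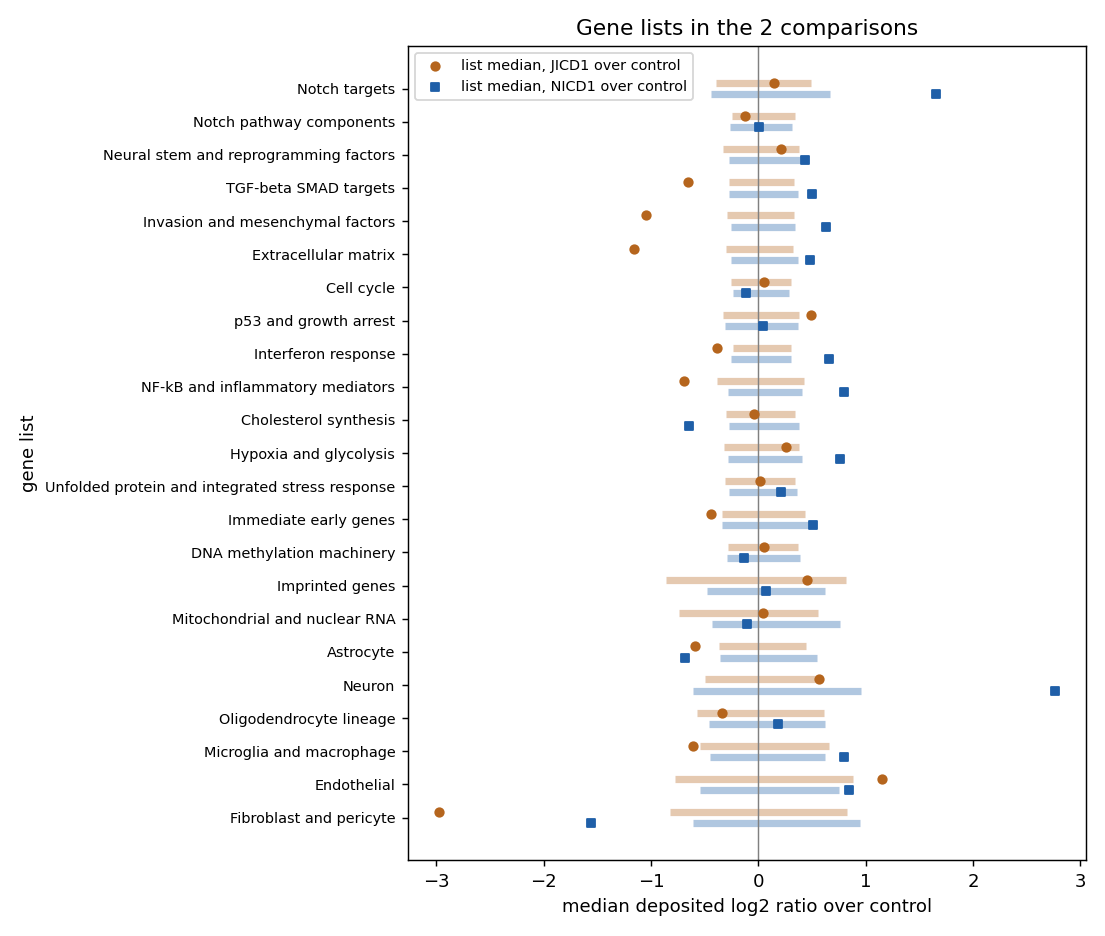
Median deposited log2 ratio (x axis) of each gene list (y axis), with circles for JICD1 and squares for NICD1; bars span the central 95% of 10000 random lists matched on abundance rank. Extracellular matrix stands at -1.16 with JICD1 and 0.48 with NICD1, and Notch targets at 0.14 and 1.66.

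The third comparison set the constructs against each other. Both tables use the same control, so subtracting the ratios gives JICD1 over NICD1, a value with no score and no test. Of 850 genes present in both tables and scored in at least one, 598 differed by a log2 of 1 or more, 167 higher and 431 lower in the libraries labelled JICD1 than in the NICD1 libraries. Notch targets had a median difference of -1.76, TGF-beta and SMAD targets of -1.69, matrix genes of -1.64, NF-kB genes of -1.42 and invasion genes of -1.30, each below all matched random lists. From the authors' deposited tables the differences were -2.13 for Hes1, -4.03 for Hey1, -3.79 for Nrarp, -6.15 for Plau and -5.45 for Acta2. In all, 14 of 23 lists lay outside the central 95%, 11 below and 3 above. The p53 list was among those above by its median (0.38, percentile 99.1) but had a mean of -0.67. The Notch target difference came inside the central 95% among genes in the upper part of the abundance ranks.

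Genes scored in both comparisons went mostly the same way. Of 174 such genes, 61 were higher and 99 lower with both constructs and 14 went opposite ways. Shared higher genes in the authors' deposited tables included Gpc4 (8.96 and 8.63), Snai2 (4.45 and 4.50) and Map2 (3.02 and 3.95), in the order JICD1 and NICD1. Shared lower genes in the authors' deposited tables included Rbp2 (-9.45 in both), Cldn9 (-5.98 and -7.82) and Tgfbi (-4.88 and -2.92). Independent lists would share 3.39 higher and 3.39 lower genes and have 7.61 going opposite ways, so the 14 opposite genes also exceed that number. Of those 14, 13 were lower with JICD1 and higher with NICD1, against 5.54 for independent lists. The shared control alone raises the count of genes going the same way. When the 3 group values were relabelled at random within each gene, genes chosen by size of ratio shared a direction in 180 to 223 cases over 100 relabelings, against 256 chosen the same way from the real ratios. Across the 18182 genes of both tables, which are not independent replicates, r was 0.525 and rho 0.42; relabelled values of r were 0.480 to 0.520, all below the observed r. The covariance was 1.06 against 0.99 after relabelling, a difference of 0.07. The variance of the log2 ratios was 1.99 for JICD1 over control, 2.06 for NICD1 over control and 1.92 for JICD1 over NICD1. The constructs thus differed from each other nearly as much as from control. The 3 control libraries could not be divided, so part of the excess may come from the shared control.

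Whole chromosomes also differed. In the libraries labelled JICD1 the 732 genes of chromosome 3 had a median log2 ratio of 0.53 and the 605 genes of chromosome 15 had -0.45, while with NICD1 these medians were -0.01 and -0.05. The 505 genes of chromosome 19 had medians of 0.19 with JICD1 and 0.45 with NICD1. All medians beyond 0.1 among these lay outside 10000 random gene sets. Of the genes named above, Sox2, Hey1, Bhlhe22, Stmn2, Tram1l1 and Vcam1 lie on chromosome 3, Ctnnd2 and Has2 on chromosome 15, and Acta2, Syt7 and Il33 on chromosome 19. Relative to the chromosome median, Sox2 stood at 0.92 in the JICD1 comparison.

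**Figure D3:**
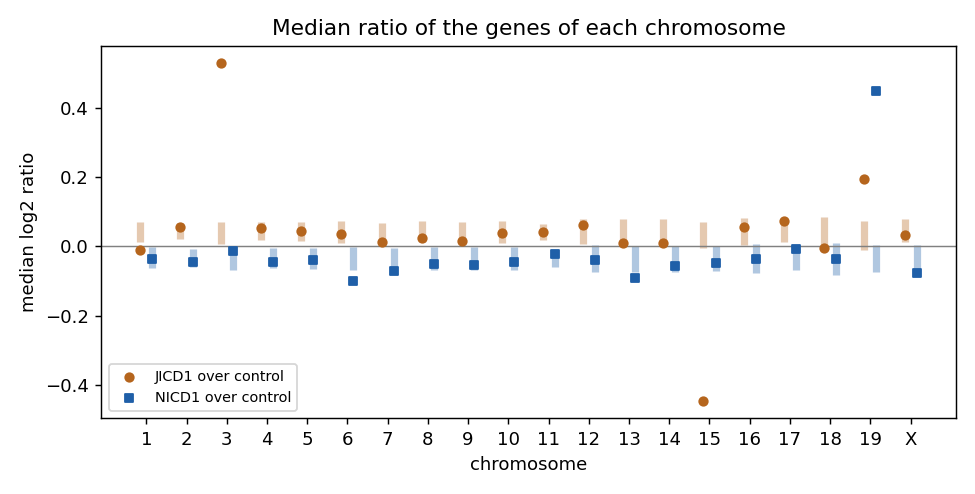
Median deposited log2 ratio (y axis) of the genes of each chromosome (x axis), with circles for JICD1 and squares for NICD1; bars span the central 95% of random gene sets of the same size. Chromosomes 3 (0.53) and 15 (-0.45) stand apart with JICD1 and chromosome 19 (0.45) with NICD1.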

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

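An absolute log2 ratio of at least 1, a setting fixed before the data were examined, kept every count within 1.5 times (532 genes for JICD1, 500 for NICD1, 595 between the constructs, 160 shared). That setting could remove almost nothing, as the smallest absolute log2 ratio of a scored gene was 0.9988 for JICD1 and 0.9758 for NICD1. The count between the constructs already asked for a difference of 1. All other alternatives were chosen after the data were examined. The counts depend on the score threshold, by its construction: at 0.9 they were 125 for JICD1, 118 for NICD1, 185 between the constructs and 27 shared, and at 0.7 they were 1633, 1508, 1122 and 463. The share of higher genes moved with it, from 203 of 533 to 793 of 1633 for JICD1 and from 316 of 503 to 90 of 118 for NICD1. Leaving out genes at the floor, leaving out chromosomes 3, 15, 19 and Y, or subtracting chromosome medians kept each of these counts within 1.5 times. These settings could move the counts little. Few scored genes had the control or the transfected group at the floor (5 and 13 for JICD1, 17 and 5 for NICD1). The left-out chromosomes held 732, 605, 505 and 8 genes with no group at the floor, a small part of 18182. Subtracting medians does not alter the score, which defines a scored gene. Of 23 lists, those outside the central 95% numbered 12 for JICD1, 15 for NICD1 and 14 between the constructs. With the tables' own symbols only, which removes most genes, they numbered 6, 7 and 9, and among genes in the upper part of the abundance ranks 9 for NICD1. Lists left with fewer than 5 members by such a setting were not compared, so these counts need not be out of 23. The astrocyte median changed sign with the tables' own symbols, to 0.022 for JICD1 and 0.70 for NICD1, over 7 members; the cause was not tested. Of 41 list results outside the central 95%, 26 were outside under every alternative that could be run for them (up to 5), including the TGF-beta, invasion and matrix lists with JICD1 and the Notch target and cholesterol lists with NICD1. Of 193 named gene values, 0 scored ones changed sign relative to the chromosome median. No scored value could have done so, as scored absolute log2 ratios were at least 0.9758 and the largest chromosome median was 0.9446. No paired analysis was possible because the deposited tables hold 1 ratio per gene for a whole group and no value per replicate. For the same reason the other settings fixed beforehand were not run: normalization, tool, filters on low values, pseudocount, left-out libraries, one fit of all libraries, an estimated inter-gene correlation and a rotation test of lists. The depth is unknown, so its limit on genes of low abundance cannot be given.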

Other observations

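The gene groups of this paragraph and the next were picked after their values were seen, 6 in all, and their percentiles describe the pick. Histone genes picked by symbol had a median log2 ratio of 0.52 over 36 genes with JICD1, above the central 95% of matched random lists. With NICD1 their median was -1.07 over 34 genes, below all matched random lists. H1f2 (2.74) and H2bc4 (2.96) were scored with JICD1 in the authors' deposited table. Keratin genes had medians of -1.50 with JICD1 and -0.71 with NICD1, and Krt14 stood at -6.16 and -5.82 in the authors' deposited tables. Akr1c genes, which encode aldo-keto reductases, had medians of -3.23 and -2.29. Hox genes had medians of 0.02 and -0.71, with Hoxa10 at -2.33 and -6.48 in the authors' deposited tables; Hoxb6 was scored higher with JICD1, at 3.35.

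The 4 measured Prl2c genes, a family of prolactin-related genes, were all scored higher with NICD1, with a median of 5.29, against -0.20 with JICD1; they are related copies, and how reads shared between them were counted is not given in the sources used here, so single members are uncertain. A set of 8 repeat-like predicted genes including Gm10800 (2.77) and Gm10801 (2.77 in the authors' deposited table) had a median of 2.77 with JICD1 and, over 6 of them, -1.45 with NICD1. Whether these genes share reads was not examined. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y stood at 1.51, 1.35, 1.32 and 1.25 with JICD1 and at 0.91, 0.92, 1.16 and 1.09 with NICD1 in the authors' deposited tables. The other Y genes measured went otherwise, with Uba1y at -0.15 and 0.14, Rbmy at 0.50 and -5.14, Gm3376 at 0.64 and -5.03 and Gm20775 at -1.01 and -0.32 for JICD1 and NICD1 in the authors' deposited tables. Chromosome 15 had medians of -0.40, -0.44 and -0.50 in the first, middle and last parts of its genes by order, of about equal size, with JICD1, and chromosome 19 had 0.52, 0.42 and 0.42 with NICD1.

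Of the tests that follow, those of a chromosome gain, of the control cells, of fibroblast-like cells and of a matrix response were written after the result was seen. Genes of chromosome 3 were higher in the libraries labelled JICD1. GC content argues poorly as the cause, since the median stayed at 0.49 (0.4875) after genes of like GC content were subtracted. Responses of single genes would leave the lower tail in place, but the 10th percentile of its 489 genes in the upper part of the abundance ranks lay 0.65 above that of the other chromosomes, against -0.32 to 0.29 for the central 95% of random gene sets. A candidate explanation is gain of a whole chromosome 3 in those cells: the first, middle and last parts of its genes by order each had a median of at least 0.49 (0.4894), and NICD1 had -0.01. DNA was not analysed here, so this remains a hypothesis. If it holds, ratios of genes on chromosome 3 such as Sox2 could hold a copy number part that is no response to the construct. After the same GC subtraction chromosome 15 stood at -0.48 with JICD1 and chromosome 19 at 0.48 with NICD1. The same doubt could apply to genes there, such as Ctnnd2 with JICD1 and Il33 with NICD1, but it was not tested.

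The 160 genes scored in both comparisons in the same direction are hard to weigh. Use of one control value in both ratios could give many of them: relabelled groups gave 180 to 223, a range that lies above 160 and was counted by size of ratio instead of by score, so the prediction as written decides nothing. Counted by size on both sides, the real ratios gave 256, above the highest relabelled count, but this way of counting was chosen after the prediction. A difference of the control cells that neither construct made cannot be told apart from a response to both, since there was 1 control group; the Y-linked genes had medians of 0.52 with NICD1 and 0.94 with JICD1 over 8 genes.

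Matrix genes were lower in the libraries labelled JICD1. Fewer fibroblast-like cells in these libraries stay open: all 6 fibroblast and pericyte markers lay below 0, while the 27 fibroblast and matrix genes in the upper part of the abundance ranks had an interquartile range of 2.17, which argues against a common amount only if the other cells do not express them. Chromosome-wide shifts could add little to this list, as Postn alone of the measured matrix genes lies on chromosome 3, 15 or 19. Subtracting chromosome medians could therefore hardly move the matrix median, which stayed at -1.22. A response of matrix and SMAD target genes to JICD1 remains open, as the SMAD target list also had a median of -0.66. Each construct has 1 ratio per gene, and whether libraries of a group came from separate cell pools is not given in the sources used here. Such a response therefore cannot be told apart from a difference between the transfected cell pools.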
